A study of Mus musculus with 2 samples.

How the data were processed

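DNase-seq was done on tissue labelled as a layer of the hippocampus in 1 field and as hippocampus in another, from 2-month-old female B6CASTF1/J mice, per the labels, in 2 libraries labelled as biological replicates 1 and 2 of 1 group. Both carry the same donor record and separate biosample records, per the labels. The labels do not say whether the pieces came from different animals, so the spread between replicates may be technical. Each library has 2 peak lists, a footprint list and a list of bases with their FDR, all deposited by the authors on mm10 (GRCm38), per the labels. The aligner, peak and footprint callers and their versions are not given in the sources used here. Peaks were listed per library, not on pooled libraries, per the descriptions deposited with the files.

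The peak value is a signal deposited by the authors. Tested on the files, each value below 1 was a whole multiple of 1 step per library (100% within 0.05 steps), so it is scaled to the library; the scale is not stated, and the tag numbers given assume a value per M tags. Values were used to rank and describe peaks, and ratios between libraries rest on that scale. The deposited base lists hold FDR values (read here as q-values) and list only bases under 0.05. In the shorter peak list each peak's lowest listed FDR was under 0.001, as tested on the files. In the longer one it was under 0.05, which was bound to hold because no other bases are listed. The value in the deposited footprint lists was 0.01 on every line, read as an FDR threshold and not used.

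Annotation was GENCODE M21 on GRCm38, and sequence was the RefSeq GRCm38.p6 assembly; all peaks lay within its chromosome lengths. A promoter peak overlapped the 1 kb on either side of a TSS of a protein-coding transcript, and other peaks were called distal. Noncoding list members such as Xist were judged at their own TSS. A gene's promoter value was the highest peak value there. Genes that share a promoter share its peak. Peaks were compared at an overlap of at least 1 bp and with 100 random placements on the same chromosomes outside assembly gaps. Shares carry 95% Wilson intervals. Reads of an F1 hybrid were placed on the C57BL/6J assembly, per the build in the labels, and how CAST/EiJ alleles were handled is not given in the sources used here.

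Gene lists (26), motif consensuses (21), tests, alternatives and the rule for named genes were fixed before the data were examined. Lists were tested on promoters accessible in both libraries against all other protein-coding genes with Fisher's exact test, and on shared distal peaks in the gene and 10 kb on each side against 10000 random lists of the same region length deciles, both two-sided with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Genes are the units of these tests, not animals. Motifs were searched on either strand within 20 bp of footprint middles and in windows moved by 100 bp to either side, with Fisher's exact test. Footprints that lie close together share windows, so motif intervals are too narrow. Median peak width was 196 and 200 bp, so moved windows can lie at or beyond the edge of the peak. The odds ratios therefore do not separate footprints from the accessible sites that hold them. Named genes were, per list, the 2 with the highest mean promoter value among those with a peak in both libraries and the first 2 in alphabetical order with none; the 10 genes with most shared distal peaks; the 5 strongest shared distal regions by mean rank; and per library the 5 strongest promoters with no peak in the other. The Y-linked list and Xist were always named. Some genes that this rule takes are not reported here. Other names, such as Eno2 and the genes with a peak in replicate 1 only, were chosen after their values were seen. Of the listed symbols 1, Ahsp, was not found in the annotation, and 1 was matched through a RefSeq synonym.

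Alternatives were the shorter peak lists, a reciprocal overlap of 50%, equal numbers of peaks, promoter windows of 500 bp and 2.5 kb, flanks of 0 and 50 kb, a background matched on quintile of promoter CpG observed over expected, an FDR of 0.01, a motif flank of 10 bp, windows moved by 200 bp and each replicate left out. Procedures were tested on simulated data. Of 100 lists of 14 genes simulated with 95% accessible promoters 81.0% were called at an unadjusted exact p under 0.05, and 5.00% of 100 unchanged lists; for distal peaks at 3 times the mean the shares were 89.0% and 4.00%. A motif planted in 1% of simulated windows raised its share by 0.995 percentage points, and of simulated peaks of which 60.2% were copied 60.2% were found shared. Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6, and bedtools 2.31.1 for reciprocal overlaps.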

Results

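DNase I cuts DNA where it is not packed into nucleosomes or covered by protein, and sequencing of the cut ends (DNase-seq) maps accessible chromatin. The assay was applied to tissue that 1 label calls a layer of the hippocampus and another hippocampus, with the dissected part not stated, from female B6CASTF1/J mice (offspring of a C57BL/6J and a CAST/EiJ parent) aged 2 months. The labels give 1 group of 2 biological replicates, each with 1 library, so there was no comparison between conditions. The comparisons are between replicates, between gene lists and all other genes, between footprints and neighbouring sequence, and between chromosomes. Replicate 1 had 129779 peaks covering 24.5 Mb in the longer of its deposited peak lists, and replicate 2 had 71895 peaks covering 14.6 Mb. Median peak width was 196 bp in replicate 1 and 200 bp in replicate 2. The shorter lists held 76841 and 38710 peaks. Read depth is not stated in the sources used here. Peak values were whole multiples of 1 step per library, and if the scale is per M tags the steps stand for 113 M and 96.9 M tags. With 2 libraries, no p-value was computed across libraries. Intervals on shares cover counting error only.

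Promoters of genes of excitatory neurons were accessible in both libraries. All 14 members of the forebrain glutamatergic list had a peak within 1 kb of a transcription start site (TSS) in both libraries, against 59.0% of other protein-coding genes (adjusted p = 0.00227, Fisher's exact test, two-sided, Benjamini-Hochberg over 26 lists). Of the pan-neuronal list, 13 of 14 promoters were accessible in both libraries (adjusted p = 0.0250, exact), led by Syt1, the calcium sensor of synaptic vesicle release, at 4.46 ± 1.35 (SD, n = 2) and Tubb3, a neuronal tubulin, at 3.59 ± 0.875 (SD, n = 2). Syt1 lies at 108497650 to 109010982 on chromosome 10 and Tubb3 at 123411424 to 123422015 on chromosome 8 (GRCm38). Eno2 was the pan-neuronal member with a peak in replicate 1 only, at 2.08. With genes of the same promoter CpG quintile as background, the glutamatergic list kept its call (adjusted p = 0.00115, exact) and the pan-neuronal list lost it (adjusted p = 0.0638, exact), at a difference of 21.7 percentage points against 33.9.

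All 17 activity-regulated genes, which neurons induce after stimulation, had a promoter peak in both libraries (adjusted p = 0.00107, exact). Jun had the highest value, 14.7 in replicate 1 and 7.25 in replicate 2, followed by Egr1 with a mean of 6.10 ± 0.810 (SD, n = 2). These genes also had more distal peaks than random lists matched on region length. On average 2.41 peaks shared by both libraries lay in the gene or within 10 kb of it and outside the 1 kb on either side of protein-coding TSSs, against 0.688 in random lists, a 3.51-fold difference (adjusted permutation p = 0.0013; the unadjusted permutation p of 0.0002 is the smallest that 10000 random lists can give, two-sided). Of the 17 genes, 16 had at least 1 such peak, with 5 at Fosb and 4 each at Egr1 and Junb. The promoter call was lost against genes of the same CpG quintile (a difference of 15.2 percentage points, adjusted p = 0.114, exact). The distal call was lost with no flank around the gene (2.55-fold, adjusted permutation p = 0.139) and kept under the other alternatives, at 2.35-fold to 4.20-fold.

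Lists of hippocampal subfield markers did not pass the test over both libraries, although the dentate and the CA3 and CA2 lists each stood 21.0 percentage points above other genes. With 10 members per list the test had little power. With a window of 2.5 kb, 9 of 10 dentate promoters, 28.1 points above other genes, still did not pass (adjusted p = 0.146, exact). With the shorter peak lists 5 of 10 dentate promoters were accessible, at -3.17 points. Against genes of the same CpG quintile the dentate difference shrank to 5.37 points. The CA3 and CA2 list stood at 16.3 points against that background and at 6.84 with the shorter peak lists. Of the dentate granule cell list, 8 of 10 promoters were accessible in both libraries, with C1ql2 at 2.09 ± 0.533 (SD, n = 2) and Calb1, a calcium-binding protein, at 1.74 ± 0.229 (SD, n = 2). Lct and Pdzd2 had no promoter peak in either, although 19 shared distal peaks lay in or near Pdzd2. Of the CA3 and CA2 list, 8 of 10 were accessible in both, led by Nectin3 at 3.65 ± 0.283 (SD, n = 2) and Pcp4 at 3.15 ± 0.0403 (SD, n = 2), and Iyd had no peak in either (adjusted p = 0.265 for each of these lists, exact). Of the CA1 list, 6 of 10 were accessible in both and 10 of 10 in replicate 1. Wfs1 had 4.44 ± 1.40 (SD, n = 2) and Man1a 3.33 ± 0.0598 (SD, n = 2), while Fibcd1, Gpr161, Dcn and Spink8 had a peak in replicate 1 only, and in replicate 1 alone the list was higher than other genes (adjusted p = 0.0404, exact). GABAergic interneuron markers were accessible in both libraries at 5 of 15 promoters (adjusted p = 0.0963, exact). Gad1, which makes the transmitter GABA, had 1.37 ± 0.176 (SD, n = 2), and Gad2 and Lhx6 had no peak in either library. The GABAergic list was lower against genes of the same CpG quintile and with the shorter peak lists (adjusted p = 0.00667 and 0.00819, exact). In replicate 1 alone 9 of its 15 promoters had a peak, -3.42 percentage points from other genes against -25.7 over both libraries (adjusted p = 0.825, exact).

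**Figure D1:**
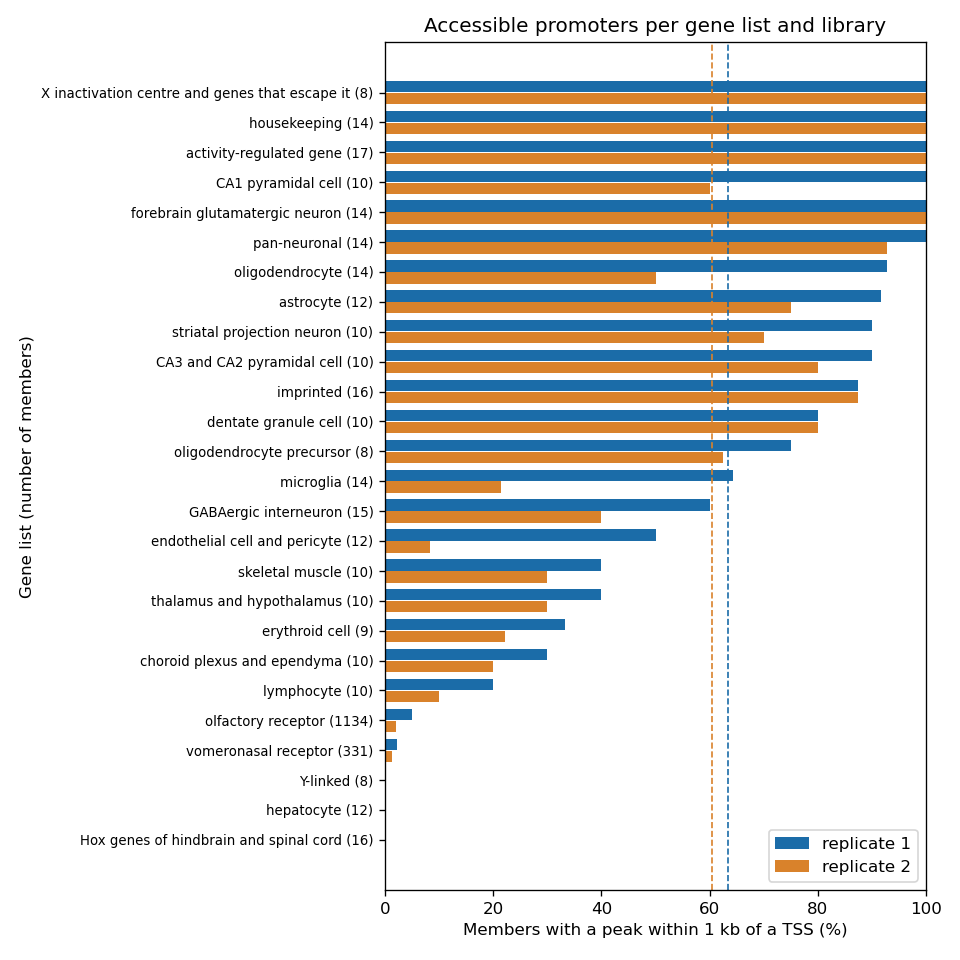
Share of the members of each gene list with a peak within 1 kb of a TSS (x axis, percent), 1 bar per list and library; the number of members stands after each list's name and the dashed lines give the share over all protein-coding genes, 63.4% in replicate 1 and 60.4% in replicate 2. Microglia members with a peak numbered 9 of 14 in replicate 1 and 3 of 14 in replicate 2, and Hox, hepatocyte and Y-linked members had none in either library.

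Fewer promoters of glial and vascular markers had a peak in replicate 2 than in replicate 1. Over all protein-coding genes the share went from 63.4% to 60.4%. Some neuronal lists also fell, CA1 from 10 to 6 of 10 and GABAergic from 9 to 6 of 15. The pan-neuronal list went from 14 to 13 and CA3 and CA2 from 9 to 8. The dentate (8) and forebrain glutamatergic (14) lists stayed the same. Astrocyte genes went from 11 to 9 of 12 and oligodendrocyte precursor genes from 6 to 5 of 8. Of 14 oligodendrocyte genes, 13 had a peak in replicate 1 and 7 in replicate 2. Myrf, a regulator of myelin genes, had 1.54 ± 0.532 (SD, n = 2) and Olig1 1.44 ± 0.159 (SD, n = 2). The myelin genes Mog, Mag and Mobp had a peak in replicate 1 only, while Mbp, Cnp, Cldn11 and Ugt8a had one in both libraries. Of 14 microglia genes, 9 had a peak in replicate 1 and 3 in replicate 2. Irf8 had 1.65 ± 0.0314 (SD, n = 2). Aif1 and C1qb had none, and P2ry12, Tmem119, Csf1r, C1qa, Trem2 and Siglech had one in replicate 1 only. Of 12 endothelial and pericyte genes, 6 had a peak in replicate 1 and only Pdgfrb, at 0.691 ± 0.160 (SD, n = 2), in both. Cldn5 and Flt1 had none. Counted over both libraries, the microglia list (adjusted p = 0.0130, exact) and the endothelial list (adjusted p = 0.00178, exact) were lower than other genes. In replicate 1 alone neither was (adjusted p = 1 and 0.424, exact), at differences of 0.867 and -13.4 percentage points against -37.6 and -50.7, so both calls rested on replicate 2. Against genes of the same CpG quintile the endothelial call was kept (adjusted p = 0.00115, exact) and the microglia call lost (adjusted p = 0.435, exact), at -13.4 points. Among astrocyte genes 9 of 12 were accessible in both libraries, led by Id4 at 3.91 ± 1.22 (SD, n = 2) and Sox9 at 2.71 ± 1.06 (SD, n = 2), with none at Gfap. Among oligodendrocyte precursor genes 5 of 8 were, led by Tnr at 2.21 ± 0.850 (SD, n = 2) and Pdgfra at 1.58 ± 0.0905 (SD, n = 2), with none at Cspg4 or Neu4. Neither list passed the test, and nor did the oligodendrocyte list (adjusted p = 0.450, 1 and 0.639, exact), although the oligodendrocyte list was lower with the shorter peak lists (adjusted p = 0.0461, exact). Its difference from other genes was -9.01 percentage points over both libraries, -31.8 with the shorter lists and 29.5 in replicate 1 alone (adjusted p = 0.0521, exact).

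Promoters of genes of other tissues were mostly without peaks. None of 16 Hox genes of the hindbrain and spinal cord (adjusted p = 5.47e-06, exact), among them Hoxa2, and none of 12 hepatocyte genes (adjusted p = 0.000146, exact), among them Alb and Apoa1, had a promoter peak in either library. Of 1134 olfactory receptor genes 18 had one in both libraries (1.59%), and of 331 vomeronasal receptor genes 1 had (0.302%). In single libraries the numbers were 56 and 23 olfactory and 7 and 4 vomeronasal receptors. Against genes of the same CpG quintile the difference of the olfactory receptors shrank from -60.6 to -10.6 percentage points and that of the vomeronasal receptors from -59.6 to -10.9 (adjusted p = 4.42e-46 and 2.60e-16, exact). Shared distal peaks around these receptors were 0.112 and 0.0436 times as frequent as in random lists (adjusted permutation p = 0.0013 for each, two-sided). Under the alternatives these values ran from 0.0472 to 0.204, the latter in replicate 1 alone, and from 0.0223 to 0.0957, the latter in replicate 2 alone. The lymphocyte list, with Pax5 as its accessible member of 10 at 0.877 ± 0.0729 (SD, n = 2) and none at Cd3e, was lower (adjusted p = 0.00535, exact), with 2 of 10 in replicate 1 alone. The choroid plexus and ependyma list was lower with 2 of 10, Foxj1 at 5.12 ± 1.14 (SD, n = 2) and Ttr at 0.760 ± 0.126 (SD, n = 2, the middle of its replicate 1 peak 1001 bp from the TSS), with none at Aqp1 or Clic6 (adjusted p = 0.0393, exact). Calls of the hepatocyte, lymphocyte and choroid plexus lists were lost against genes of the same CpG quintile (adjusted p = 0.136, 0.369 and 0.0746, exact), at differences of -22.0, -18.8 and -27.5 percentage points against -59.0, -49.0 and -39.0. The call of the choroid plexus list was lost also in replicate 1 alone (adjusted p = 0.0815, exact), at -33.4 points.

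The lists of striatal, thalamic and hypothalamic, muscle and erythroid genes did not pass the test (adjusted p = 0.611, 0.141, 0.141 and 0.0611, exact). Striatal projection neuron genes had 7 of 10 accessible promoters, with Rgs9 at 2.90 ± 1.02 (SD, n = 2), Drd1 at 1.90 ± 0.355 (SD, n = 2) and none at Isl1. Thalamus and hypothalamus genes had 3 of 10, with Hcrt at 2.35 ± 0.849 (SD, n = 2, the middle of its replicate 1 peak 1007 bp from the TSS), Tcf7l2 at 0.939 ± 0.0729 (SD, n = 2) and none at Avp or Gbx2; this list was lower against genes of the same CpG quintile (adjusted p = 0.00667, exact). Skeletal muscle genes had 3 of 10, with none at Acta1 or Ckm. The peaks at Mylpf (5.86 ± 3.38, SD, n = 2) and Actn3 (5.37 ± 0.426, SD, n = 2) also lay within 1 kb of a TSS of Tbc1d10b and Zdhhc24, and the peak at Actn3 was nearer to Zdhhc24, 41 bp against 722 bp. Erythroid genes had 2 of 9, with Epor at 2.09 ± 0.358 (SD, n = 2) and none at Alas2 or Gata1. With a window of 500 bp the thalamus and hypothalamus, muscle and erythroid lists were lower (adjusted p = 0.0332, 0.00628 and 0.0114, exact), the erythroid list also with the shorter peak lists (adjusted p = 0.0269, exact). Housekeeping genes had 14 of 14, led by Actb at 8.82 ± 2.21 (SD, n = 2) and Rpl13a at 8.53 ± 3.27 (SD, n = 2), which passed (adjusted p = 0.00227, exact), also against genes of the same CpG quintile (adjusted p = 0.0265, exact).

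On the sex chromosomes, Xist, the RNA that coats the inactive X, had a promoter peak in both libraries, at 0.964 in replicate 1 and 0.949 in replicate 2. All 8 genes of the X inactivation centre and of escape from inactivation had one (adjusted p = 0.0427, exact), led by Kdm6a at 12.8 ± 4.31 (SD, n = 2) and Ftx at 7.04 ± 3.08 (SD, n = 2). In replicate 1 alone this call was lost (adjusted p = 0.0619, exact) although all 8 had a peak there, a difference of 36.6 percentage points. It was lost also with the shorter peak lists (adjusted p = 0.102, exact), where 7 of 8 had a peak, a difference of 34.3 points. The CpG background covers only the 4 protein-coding members, at 7.41 points (adjusted p = 1, exact). None of the 8 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d, Uty, Sry, Zfy1, Zfy2 and Usp9y) had a promoter peak (adjusted p = 0.00230, exact) or a distal peak shared by both libraries, although 1 of them had a distal peak in replicate 1. No promoter peak lay at any of the 183 protein-coding genes of chromosome Y (95% Wilson interval 0 to 2.06%). Chromosome Y held 39 peaks in replicate 1 and 34 in replicate 2. Peak density on X was 0.383 and 0.389 of that on the autosomes, and 48.0% (44.8 to 51.2) and 46.0% (42.8 to 49.2) of X-linked protein-coding genes had a promoter peak, against 64.7% (64.0 to 65.3) and 61.6% (60.9 to 62.2) of autosomal ones. Of 16 imprinted genes 14 had a promoter peak in both libraries (adjusted p = 0.0395, exact), led by Ube3a at 6.82 ± 0.436 (SD, n = 2) and Peg3 at 4.93 ± 2.15 (SD, n = 2, a peak also within 1 kb of a TSS of Usp29), with none at H19 or Igf2. That call was lost in either library alone (adjusted p = 0.109 in replicate 1 and 0.0607 in replicate 2, exact), at differences of 24.1 and 27.2 percentage points against 28.5 over both. It was lost also with the shorter peak lists (21.9 points, adjusted p = 0.169, exact) and with the CpG background over its 12 protein-coding members (23.0 points, adjusted p = 0.0638, exact).

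Long genes held the most shared distal peaks, counted without scaling to length. Dlg2, a synaptic scaffold gene of 1973 kb on chromosome 7, had 43 shared distal peaks, and Lsamp, a cell adhesion gene on chromosome 16, had 40. Asic2 had 37, Rbfox1 35, and Auts2 and Nrxn3 34 each. The highest numbers stood at the gene models of Gm20388, with 170 over 4435 kb, and Fgfr2, with 87 over 2961 kb in this annotation, and Gm37240 had 32. Over all 21853 protein-coding genes the median was 1 shared distal peak, and 52.1% had at least 1. The strongest shared distal region lay at 39846781 to 39846920 on chromosome 17, over an annotated ribosomal RNA gene, with values of 28.3 and 48.6. The next lay at 99735641 to 99735920 on chromosome 15 in an exon of Cers5, 10.2 kb from the nearest protein-coding TSS, that of Cox14, with 23.1 and 32.4. The others were at 5860361 to 5860530 on chromosome 3 (intergenic, nearest Gm8797), 123461881 to 123462140 on chromosome 9 (in an exon of Lars2, nearest Limd1) and 49236421 to 49236620 on chromosome 6 (intergenic, nearest Igf2bp3). Of the 31-mers in the strongest region 82.7% occur more than once in the genome, and 100%, 59.6% and 78.2% of those in the last 3, but none in the exon of Cers5.

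Replicate 1 peaks that replicate 2 shared lay in promoters more often than the others. Of the 58484 regions shared by both libraries 17915 lay in promoters and 40569 outside them. Promoters made up 19.8% (95% Wilson interval 19.6 to 20.04) of peaks in replicate 1, which was 7.04 times random placement, and 31.1% (30.7 to 31.4) in replicate 2, 10.9 times, with a mean of 25.4% ± 7.96 (SD, n = 2). Replicate 1 peaks with a partner in replicate 2 lay in promoters in 31.6% of cases and those without in 9.57%. For replicate 2 the shares were 31.2% and 30.3%. Promoters accessible in replicate 1 only numbered 964 genes, the strongest being March9 (2.35), Npff (2.24), Atn1 (2.23), S100a3 (2.19) and Stac2 (2.08). Those in replicate 2 only numbered 297, led by Gm17402 (3.16), Mst1 (3.12), Arhgef25 (2.47), Gm42517 (1.71) and Thpo (1.51).

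Of replicate 1 peaks 46.6% (46.3 to 46.9) overlapped a replicate 2 peak by at least 1 bp, and of replicate 2 peaks 83.4% (83.2 to 83.7) overlapped a replicate 1 peak, against 1.14% and 2.01% for randomly placed peaks. The base-pair Jaccard index was 35.9%. With equal numbers of the strongest peaks 69.0% were shared in either direction. Sharing rose with peak value, from 8.81% in the weakest decile of replicate 1 to 98.8% in the strongest, and from 45.0% to 99.6% in replicate 2. Across the 58484 shared regions, which are sites and not independent replicates, log2 values correlated with Pearson's r = 0.878 and Spearman's rho = 0.832; r was 0.937 in promoters, a split chosen after seeing the data, and 0.787 outside them. Bases listed under an FDR of 0.05 covered 36.1 Mb (1.36% of the genome) in replicate 1 and 21.8 Mb (0.824%) in replicate 2, and 50.6% and 83.8% of them were also listed in the other library.

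**Figure D2:**
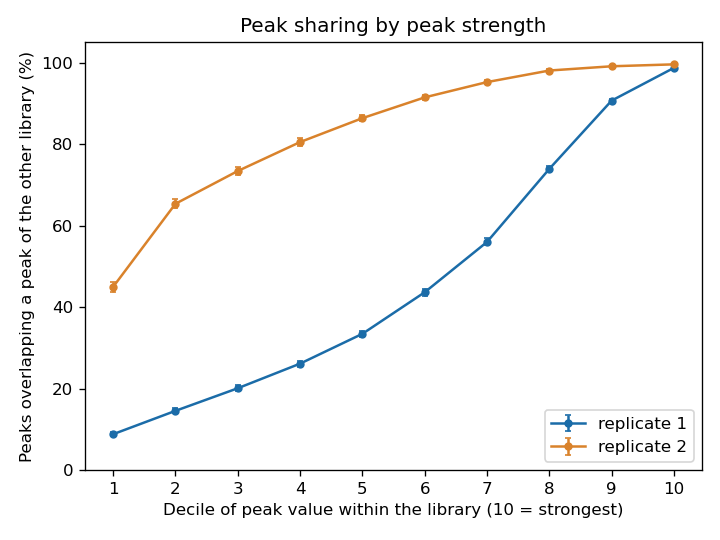
Share of peaks that overlap a peak of the other library (y axis, percent) by decile of peak value within the library (x axis, 10 the strongest); points are shares over all peaks of a decile and bars 95% Wilson intervals. The share runs from 8.81% to 98.8% in replicate 1 and from 45.0% to 99.6% in replicate 2.

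Footprints, short stretches protected from DNase I within accessible sites, held the motifs of CTCF, RFX and NFI factors and of an E-box more often than neighbouring sequence did. The CTCF consensus CCASYAGRKGGC lay within 20 bp of the middle of 2.34% of footprints in replicate 1 and 3.21% in replicate 2, against 0.105% and 0.103% of windows moved by 100 bp. The odds ratios were 22.7 (95% interval 20.7 to 24.9) and 32.1 (28.2 to 36.5). The CAGATGG E-box bound by NEUROD factors had odds ratios of 3.94 (3.82 to 4.07) and 3.55 (3.39 to 3.73), and the cAMP response element TGACGTCA 3.15 (2.83 to 3.50) and 3.48 (3.07 to 3.95). Motifs of RFX (11.1 and 11.5), NFI (8.08 and 5.81), NRF1 (3.95 and 4.82), EGR (3.26 and 2.89) and SP/KLF factors (2.04 and 1.98) were also higher in both libraries. RFX and NFI sites were rare, so their intervals were wide. RFX lay in 69 and 37 footprints (6.09 to 20.3 and 5.02 to 26.5). NFI lay in 54 and 30 (4.45 to 14.7 and 2.88 to 11.7). Smaller odds ratios were found for AP-1 (2.00 and 1.34), ETS (1.90 and 2.09), the CAGCTG E-box (1.72 and 1.52), YY1 (1.69 and 1.88) and NFY (1.30 and 1.40). GATA was lower in both (0.502 and 0.471). MEF2 (1.62 in replicate 1 and 1.30, 0.988 to 1.72, in replicate 2) passed as higher and SOX (0.746 and 0.896, 0.659 to 1.22) as lower in replicate 1 alone, with the same direction in replicate 2. With a flank of 10 bp MEF2 changed direction in replicate 2 (0.924, 0.588 to 1.45). HNF1 was found in no footprint of either library and passed as lower in replicate 1 alone, and PU.1, the left part of the REST site and a scrambled CTCF consensus passed in neither. Some of these calls depended on the setting in replicate 1. PU.1 was higher with windows moved by 200 bp (1.25, adjusted p = 3.07e-05, exact) and lower with a flank of 10 bp (0.825, adjusted p = 0.0336, exact). With windows moved by 200 bp the REST site passed as higher (1.28 against 1.26, adjusted p = 0.0337, exact) and SOX lost its call (0.825, adjusted p = 0.114, exact), both at values close to the main ones, and HNF1 lost its call with a flank of 10 bp (adjusted p = 0.196, exact). In a comparison added after seeing the data, with up to 20 other orders of the same letters, 1 order reached the odds ratio of ETS and of NFY in replicate 1 and of AP-1 and CAGCTG in replicate 2, so base composition was not excluded for these. It was not tested for RFX, NFI, NRF1, EGR, YY1 and GATA, which lay in under 500 footprints of a library. None reached that of CTCF, the CAGATGG E-box, the cAMP response element or SP/KLF in either library, although for SP/KLF only 8 other orders exist and the highest stood at 1.97 in each. The sizes depended on the comparison: with windows moved by 200 bp the geometric mean of the odds ratios of both libraries was 94.7 for CTCF against 27.0, 23.3 for RFX against 11.3, 11.7 for NRF1 against 4.36. It was 8.58 for the cAMP response element against 3.31, 5.94 for the CAGATGG E-box against 3.74, 4.14 for ETS against 1.99, 3.02 for SP/KLF against 2.01 and 2.08 for NFY against 1.35. With a flank of 10 bp it was 61.5 for CTCF, 36.3 for RFX, 9.72 for NRF1, 7.08 for the cAMP response element and 3.35 for SP/KLF. The CAGATGG E-box then had odds ratios of 6.45 in replicate 1 and 5.58 in replicate 2. By geometric mean, EGR stood at 5.58 against 3.07 and YY1 at 3.31 against 1.78, and the scrambled CTCF consensus, which passed in neither library, at 2.57 against 1.61.

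**Figure D3:**
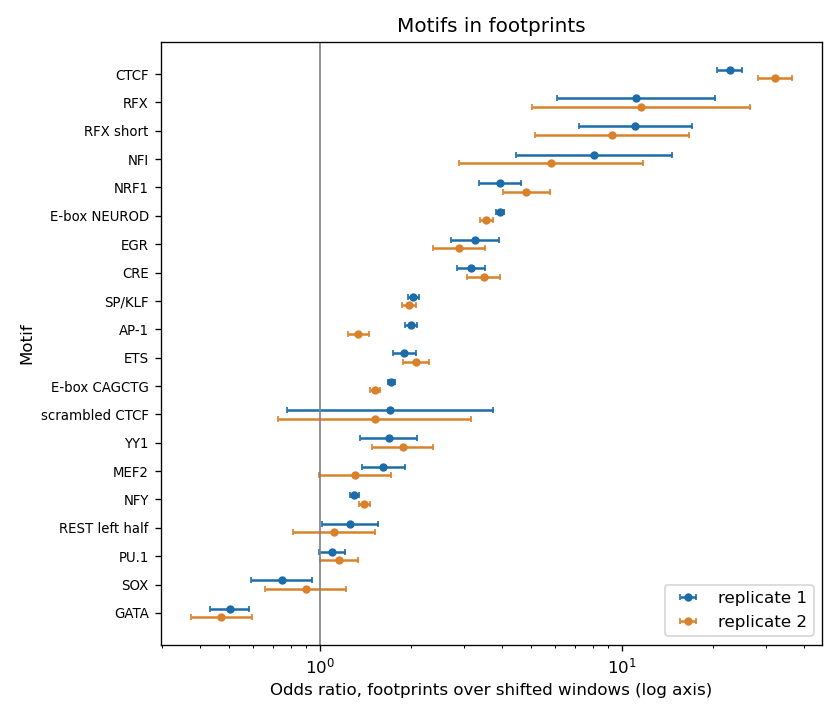
Odds ratio of each motif in footprints against windows moved by 100 bp (x axis, log scale), 1 point per library with its 95% interval; motifs in under 10 footprints of a library are not drawn. CTCF stands highest, at 22.7 and 32.1, and GATA lowest, at 0.502 and 0.471.

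The deposited files listed 227153 footprints in replicate 1 and 118610 in replicate 2, with a median width of 9 bp in each. In their own library's peaks lay 93.8% (93.7 to 93.9) and 92.6% (92.4 to 92.7), and in promoters 28.8% (28.6 to 29.0) and 42.9% (42.7 to 43.2). Overlap with a footprint of the other library was 25.8% (25.7 to 26.0) and 52.0% (51.7 to 52.2), and among footprints in peaks of both libraries 42.8% (42.5 to 43.0) and 59.3% (59.0 to 59.6).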

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

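The promoter correlations below and the permuted motif orders were chosen after seeing the data; the other alternatives were fixed before. No paired analysis was possible because there was 1 group. With the shorter peak lists, replicate 1 peaks with a partner went to 45.0% and replicate 2 peaks to 88.8%, the correlation to r = 0.889 and rho = 0.858, the promoter share to 33.5% and the X to autosome ratio to 0.343. With a reciprocal overlap of 50% the shared peaks were 35.7% and 64.5%, and with equal numbers 69.0% in each. Outside promoters r was 0.787, rho 0.756 and the X ratio 0.348; within promoters r was 0.937 and rho 0.940. Of the listed bases 74.6% were under an FDR of 0.01. With the CpG background 2 lists were higher, against 6, and 8 of 15 promoter calls were lost while 2 were gained. With no flank 0 lists had more distal peaks, against 1. Motifs lower in both libraries numbered 1, and 1 to 3 with a replicate left out. The difference of the microglia list from other genes changed sign in replicate 1 alone, to 0.867 percentage points above them, against -39.0 in replicate 2 alone. The list's share was 64.3% in replicate 1 alone against 21.4% over both libraries. That of other genes was 63.4% against 59.0%. Among lists without a call, the oligodendrocyte list went to 29.5 points in replicate 1 alone against -9.01. The signs of the CA1, dentate, astrocyte, oligodendrocyte precursor and striatal lists also changed under at least 1 alternative. The causes of these sign changes were not tested. With 2 libraries each setting that leaves one out rests on a single library.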

Other observations

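The tests on missing promoters, on partners around marker genes and on motifs by partner were chosen after the results were seen; those on chromosome Y, on repeated sequence and on the value ratios were fixed before.

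Distal peaks of replicate 1 with and without a partner in replicate 2 differed in sequence at equal peak value. Within 20 bins of value, AP-1 sites (odds ratio 1.64, 95% interval 1.54 to 1.74), GATA sites (1.87, 1.51 to 2.31), PU.1 sites (1.41, 1.22 to 1.64), MEF2 sites (1.55, 1.27 to 1.90) and the cAMP response element (1.69, 1.25 to 2.29) were more frequent in peaks without a partner. So was a less strict RFX consensus, GTTRCCATGGYAAC (2.42, 1.51 to 3.89), while the interval of the stricter RFX consensus included 1 (1.76, 0.967 to 3.21). CTCF sites (0.526, 0.489 to 0.567) and the CAGATGG E-box (0.870, 0.834 to 0.907) were less frequent in peaks without a partner. The same held for NRF1 (0.402), EGR (0.613), ETS (0.614), SP/KLF (0.821) and CAGCTG sites (0.890), each with an interval below 1. In replicate 2, peaks without a partner had fewer AP-1 sites (0.530, 0.461 to 0.609), fewer CTCF sites (0.247, 0.196 to 0.311) and fewer CAGATGG E-boxes (0.629, 0.579 to 0.685), fewer MEF2 (0.544, 0.322 to 0.921) and CAGCTG sites (0.907, 0.843 to 0.976) and more EGR sites (2.22, 1.11 to 4.43). For GATA (1.21, 0.852 to 1.72), PU.1 (0.839, 0.633 to 1.11), ETS (1.44, 0.859 to 2.43) and SP/KLF (1.03, 0.744 to 1.43) the replicate 2 intervals included 1. Both RFX consensuses, the cAMP response element and NRF1 were not estimated there, with under 10 peaks without a partner. Of the 100 strongest shared distal regions, 16 had at least 50% of their 31-mers more than once in the genome (95% Wilson interval 10.1 to 24.4%), against 1 of 100 drawn at random. Among regions with under 10% repeated 31-mers, picked after the values were seen, the strongest beside the exon of Cers5 included 58177601 to 58177820 on chromosome 13 near Ubqln1 and 98773861 to 98774200 on chromosome 11 near the clock gene Nr1d1.

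Replicate 2 had fewer peaks than replicate 1. For sequencing depth or one background factor, the median log2 ratio of peak values was compared between promoters and distal regions, and it differed by 0.10 (bootstrap interval 0.09 to 0.12) with the longer peak lists and by 0.01 with the shorter ones, both under the bound of 0.3 set before. That bound says nothing about depth, because the values are already scaled to the library and only regions called in both libraries enter the ratio. For the cell-type makeup of the 2 dissected pieces, 0 of 12 cell type lists had shared distal regions shifted by over 0.3 after adjustment, while before it the CA3 and CA2 list (0.30) and the choroid plexus list (0.47) lay beyond random lists (permutation p = 0.0400 and 0.0480, adjusted 0.288 each). The motif differences at equal peak value, such as AP-1 at 1.64 in replicate 1 and 0.530 in replicate 2, do not decide on one factor. Peaks were matched on the value in 1 library only, so those without a partner may be weaker sites than those with one. In replicate 2 they also had fewer CTCF (0.247), CAGATGG (0.629) and MEF2 sites (0.544), though more EGR sites (2.22), so the AP-1 value was not particular to AP-1. The differences set 1 library against 1 and their intervals cover counting error only. Both explanations stay open and cannot be told apart here.

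Glial and vascular marker promoters accessible in replicate 1 were missing in replicate 2 at 20 of 45 genes of 5 lists, which were grouped after seeing this. From peak value alone 10.5 would be missing, and the number was 1.90 times that (exact p = 0.000311, adjusted over 14 lists 0.00435); singly, of the 5 only microglia passed (2.54 times, adjusted exact p = 0.0203), and so did the neuronal CA1 list (3.73 times, adjusted exact p = 0.0299). Of the 5 lists, 2 stood near the number expected from value. Astrocyte genes were missing at 2 of 11 against 1.83, and oligodendrocyte precursor genes at 1 of 6 against 0.742. Matched on CpG quintile too, the group stood at 1.62 times (exact p = 0.00358, adjusted 0.0501) and the neuronal lists at 1.70 times (exact p = 0.0546), and neither microglia (1.75 times) nor CA1 (2.66 times) passed singly (adjusted exact p = 0.131 each). By the criteria first written these p-values count against weak promoters and against CpG content as the whole cause, but they are set aside because the lists were grouped after the result and genes, not libraries, are the units. For fewer glial and vascular nuclei in replicate 2, distal peaks around these genes were examined. They had a partner at -3.63 percentage points from peaks of equal value, inside the range of random lists (-9.67 to 3.91). The neuronal lists stood at -6.56, also inside their range (-7.69 to 2.47), so neither group showed a deficit beyond random lists. Among the neuronal lists, forebrain glutamatergic (-15.5) and CA1 (-18.0) lay just beyond random lists, but not after adjustment (adjusted permutation p = 0.364 each). The dentate (2.65) and the CA3 and CA2 (5.23) lists went the other way. All 3 explanations stay open and cannot be told apart with 1 library on each side.

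Peaks lay on chromosome Y in tissue from females. Reads shared with other chromosomes are a candidate source: 53.8% of the Y peaks in replicate 1 (95% Wilson interval 38.6 to 68.4) and 73.5% in replicate 2 (56.9 to 85.4), a mean of 63.7%, had at least 50% of their 31-mers on another chromosome. Of the Y peaks, 21 of 39 in replicate 1 and 9 of 34 in replicate 2 lay at the far end of the chromosome. Sequence shared with X was not counted apart from sequence shared with autosomes. The share for chromosome Y sequence at large was not computed either, so these percentages have no baseline. Male tissue in the sample would open Y-linked promoters, and 0 of the 8 Y-linked genes had a promoter peak, which argues against it at a share large enough for peaks to be called. No other explanation was tested.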
